A study of Mus musculus with 54 samples.

How the data were processed

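Total RNA of mouse aorta was hybridised on 54 two-colour arrays, with mouse embryo total RNA as the second channel of every array, per the labels. The labels name C57Bl/6 (C57) and C3H/HeJ (C3H) mice, normal chow or high-fat diet, a baseline at week 0 and later time points. Titles give weeks 4, 8, 24 and 40 on diet; the source field lists week 10 where titles say week 8, and the titles were followed. This gives 18 groups of strain, week and diet with 3 arrays each, numbered 1 to 3 in the titles. Nothing in the labels says whether arrays of a group came from separate animals or pools, so p-values measure only the spread between these arrays, which may be technical.

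The values are the deposited log10 ratios of 21446 array features on 54 arrays, where log10 is the likely base only: the deposited values stop at exactly 2 and -2, and neither base nor direction is given in the sources used here. Sizes are therefore in deposited log ratio units with the sign of the deposited table. If the ratio ran embryo over aorta, every sign would turn together. All arrays correlated positively with one another across features, with r from 0.487 to 0.966 and a median of 0.839, which is what arrays of one direction give. Dyes, scanner, background correction and within-array normalization are not given in the sources used here. Array medians lay between -0.0117 and 0.0118, so the deposited values were already centred. There were 7895 exact zeros, which is 0.682% of all values and 54 to 281 per array, and 71 values at the cap. Signal over background could not be assessed from ratios, and the number of arrays limits the precision.

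Exact zeros were treated as not measured, a choice made after the values were seen. Each array was centred on the median of the 20694 features measured on all arrays. Features with at least 2 measured values in each of the 18 groups were tested, which left 21179 and took out 267. No conversion to log2 was made, although the plan had foreseen one where base and direction were settled.

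Features carry no gene names here. The platform annotation lists 17284 of the 21446 feature numbers, 17268 of them with 1 gene symbol and 16 with several, and leaves 4162 unnamed. Its names were checked against the values and were not borne out. Across 953 pairs of features with the same symbol, the mean ratios correlated at -0.0033, and across 344 pairs with the same sequence accession at -0.0499. In 48 accessions listed at 8 or more features, the SD of the mean ratio within a set was 0.165, against 0.187 for random sets. None of 16012 other numberings brought that SD below 0.121. A group of 147 features with near-identical values, with mean ratios from -0.90 to -0.70, sat at regular numbers, and 139 of its 146 gaps were multiples of 7. The annotation names 0 of the 147, although it lists 80.6% of all features. A matching numbering could give such an absence, so it runs against the pair correlations, and the conflict was not resolved. Because features with the same name did not vary together, features are given by number only. Gene lists chosen before the data were examined were not tested.

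Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes, two-sided) to all 54 arrays, which share one estimate of the spread. P-values were adjusted by Benjamini-Hochberg over 21179 features within each comparison, and a feature was called at an adjusted p under 0.05. Comparisons were the strain difference at week 0, over 5 weeks on chow and over 4 weeks on high-fat diet; the diet difference in each strain over 4 weeks and at each week; the difference between week 40 and week 0 on chow; and their interactions. An F test asked for any change over the 5 weeks on chow. The text names, per comparison, up to 2 features with the largest positive and 2 with the largest negative difference among called features, with the same sign in every week where weeks were averaged. This replaces a longer rule written for named genes, and was set after the annotation had been checked against the values.

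The calling procedure was tested on simulated data with 200 of 20694 features changed, 50 at each size. Noise was drawn independently for each array at the feature's residual SD. The simulation therefore holds no effect of the replicate number or series. Its recovered shares and false calls apply only to arrays that vary independently. For the strain difference on chow, 90% of changes of 0.2 and 98% of changes of 0.3 were recovered, with 4 false calls among 164. For the diet difference in C57, 68% of changes of 0.2 and 94% of 0.3 were recovered, with 6 false among 152. For the time difference in C57, 22% of changes of 0.2, 52% of 0.3 and 86% of 0.5 were recovered, with 4 false among 85. For the diet difference at week 40 in C3H, 32% of 0.2, 52% of 0.3 and 82% of 0.5 were recovered, with 7 false among 92.

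The comparisons, the test and most alternatives were set before the data were examined. Alternatives set then were no centring, quantile normalization, only features measured on all arrays, no filter, the replicate number as a fixed block, the 12 series of one strain, diet and number as a random block, array weights, a trended and robust variance prior, only the arrays of the contrast with their own spread, and leaving out each array. Others were chosen after seeing the data: zeros kept as values, leaving out 5 arrays of small range, scaling arrays to one spread, removing local medians on the array grid, leaving out the 147 repeated features, a term for the arrays numbered 3, only the arrays numbered 1 and 2, only the arrays numbered 3 with week as an additive term, and array weights fitted feature by feature. These weights were added because the array weights set beforehand did not converge; a stronger prior for either kind of weight was also looked at and is not reported. The random block for series holds no term for the number, so a difference between numbers counts as spread between series. That can lower its counts for strain and diet and raise those over time. The array grid behind the local medians was assumed from the feature numbers, with 215 to a line. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.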

Results

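Aortas of C57 and C3H mice were profiled at week 0 and after 4, 8, 24 and 40 weeks on normal chow or a high-fat diet. Each of 54 arrays compared aorta RNA with one common embryo RNA, so groups are compared through their ratios to that reference. There were 18 groups of 3 arrays: 5 chow groups and 4 high-fat groups per strain. The SD of the log ratio across features was 0.266 on the median array. It was smaller on 5 arrays, at 0.160 to 0.199, and 0.225 or more on the others. These 5 were C57 chow replicate 3 at weeks 4 and 24, C57 chow replicate 2 at week 8, C57 chow replicate 1 at week 40 and C3H high-fat replicate 2 at week 4.

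Strain was visible in the arrays as a whole, but the replicate number was the strongest divider. The number accounted for a median of 24.1% of a feature's variance, against an expected mean of 3.77% with no effect. Strain accounted for a median of 2.67% (expected mean 1.89% with no effect), week for 4.82% (7.55%) and diet for 0.860% (1.89%). With no effect the median of such a share lies below its mean, most of all for strain and diet. The expected means also take no account of the variance held by the number, which leaves less for the other factors. For these reasons the medians for week and diet cannot be read as below the level of no effect. On the first principal component, which held 29.1% of the variance, the 18 arrays numbered 3 scored from -14.3 to -7.31 and the other 36 from -4.26 to 15.8. The number is balanced over groups. For the comparisons set beforehand, the count of features called is therefore given with a term for the arrays numbered 3 and from numbers 1 and 2 alone. Single weeks are given as sums, for week 8 in each strain and for week 40 in C3H. Number 3 alone holds 1 array per group, so its strain and averaged diet counts come from a fit with week as an additive term. Each strain and diet is then 1 series of arrays, and a series cannot be told apart from its strain or diet. Baseline, single weeks and changes over time were not run in number 3 alone.

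**Figure D1:**
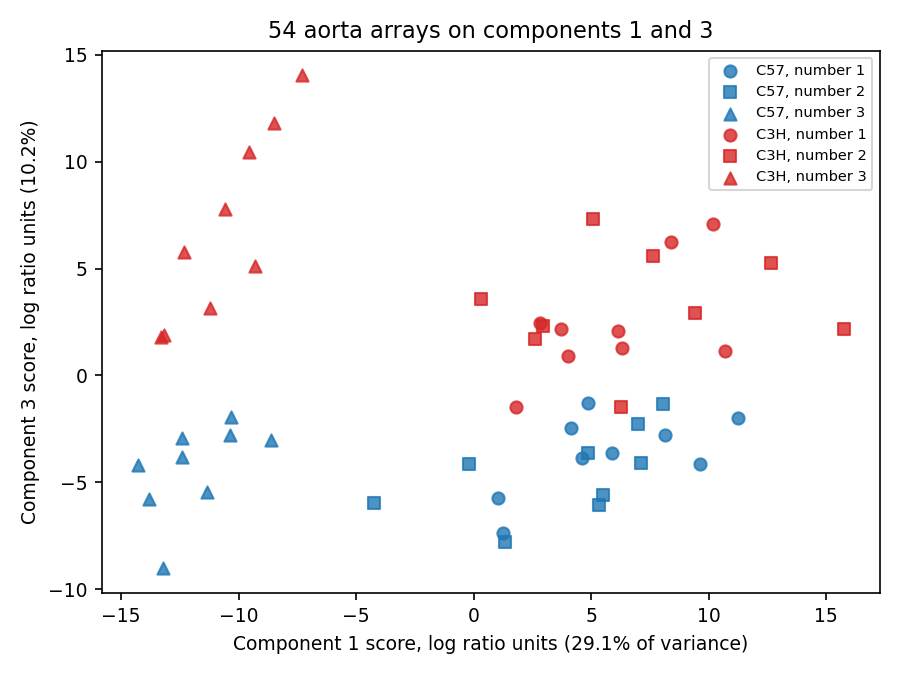
Scores of the 54 arrays on component 1 (x axis, 29.1% of the variance) and component 3 (y axis, 10.2%), in log ratio units. Colour gives the strain and the marker the replicate number; arrays numbered 3 lie at -7.31 or below on component 1.

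The first comparison asked which features differed between strains before the diet began. At week 0, feature 4881 was 1.31 higher in C57 than in C3H (SE 0.195) and feature 12763 was 0.83 higher (SE 0.109), with 3 arrays per strain. Feature 17783 differed by -1.21 (SE 0.0698) and feature 9352 by -1.10 (SE 0.0757). Their limma adjusted p-values were 5.63e-05, 4.89e-06, 1.13e-15 and 1.58e-13. In all, 113 of 21179 features were called, 67 with a higher and 46 with a lower ratio in C57. On other arrays, 109 of the 113 had the same sign on chow at weeks 4 to 40 and 102 on high-fat diet. The later chow arrays belong to the same series of strain, diet and number as the week 0 arrays and are not independent of them; the high-fat arrays come from other series. With the number 3 term 411 features were called, in numbers 1 and 2 alone 128, and with only the arrays of the contrast and their own spread 31. The count fell to 57 without C57 chow replicate 3 at week 0, to 65 without replicate 1 and to 67 without replicate 2, and to 65 without C3H chow replicate 2.

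The strain difference was then averaged over the 5 chow weeks and, on separate arrays, over the 4 high-fat weeks. Feature 4881 had a mean ratio of -0.20 ± 0.13 (SD, n = 15) in C57 and -1.51 ± 0.22 (SD, n = 15) in C3H on chow, a difference of 1.31 (SE 0.0872) on chow and 1.11 (SE 0.0975) on high-fat diet. Feature 4070 was 0.72 higher in C57 on chow and 0.73 higher on high-fat diet. Feature 17783 had a mean of -0.05 ± 0.06 (SD, n = 15) in C57 and 1.13 ± 0.11 (SD, n = 15) in C3H on chow, a difference of -1.17 on either diet. Feature 9352 differed by -1.15 on chow and -1.16 on high-fat diet. If the values are log10, the chow differences of these 4 features are 20.4-fold, 5.29-fold, 14.8-fold and 14.0-fold. Over the 9 conditions of week and diet, feature 4881 differed by 0.97 to 1.41, feature 4070 by 0.59 to 0.89, feature 17783 by -1.30 to -1.02 and feature 9352 by -1.34 to -0.94.

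**Figure D2:**
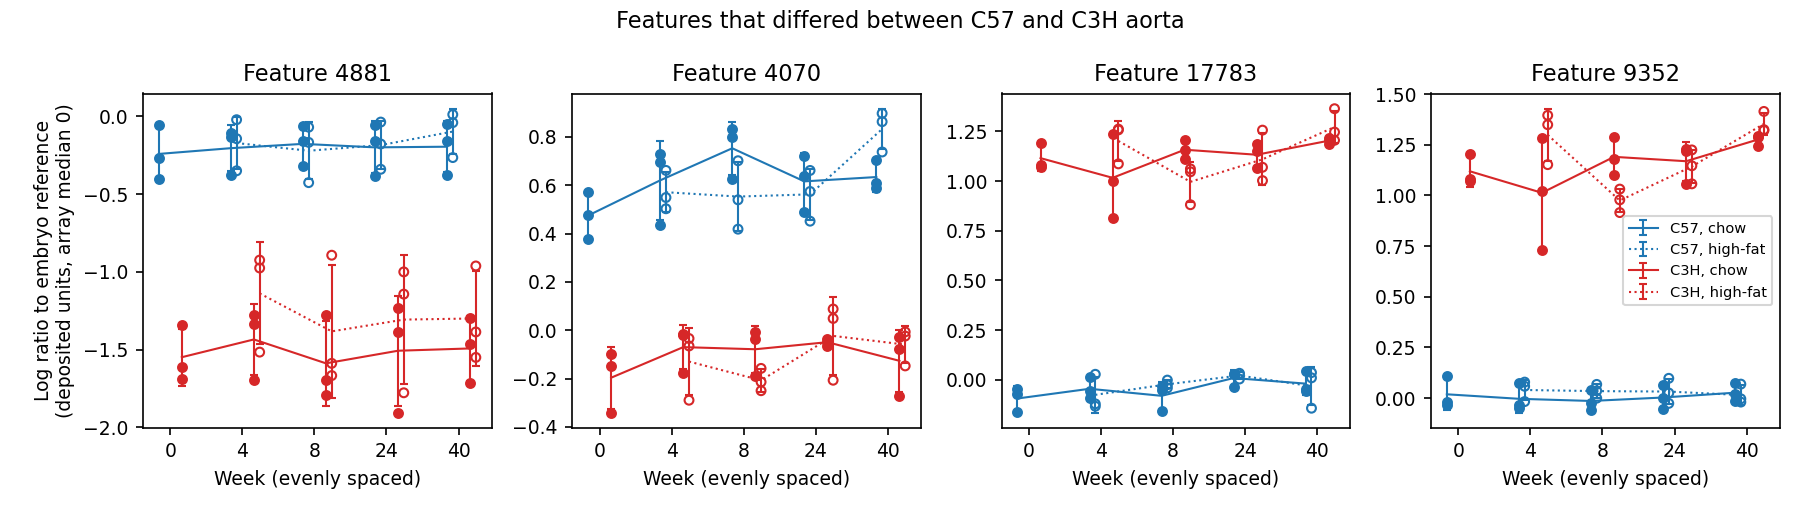
Log ratio to the embryo reference (y axis, deposited units) by week on diet (x axis, evenly spaced) for 4 features; points are arrays, lines join group means and bars are SDs of 3 arrays. In features 17783 and 9352 all C3H arrays lie above all C57 arrays, and in features 4881 and 4070 below them.

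On chow 1475 features were called, 821 higher and 654 lower in C57, and 116 of them differed by over 0.3. The median absolute difference of the called features was 0.13. On high-fat diet 2336 were called, 1000 higher and 1336 lower, and 166 differed by over 0.3. With quantile normalization the high-fat calls were 1242 higher and 1089 lower. Both lists held 867 features, 861 of them in the same direction. Of these, 541 were higher and 320 lower in C57, where independent lists would share 38.8 and 41.3. Among the 861, 825 had the same sign in all 9 conditions. In 51 features the 27 C57 arrays and the 27 C3H arrays did not overlap, 30 of them higher and 21 lower in C57. With no strain difference, the share of features expected to separate in this way is 1.03e-15 if all arrays vary independently. If the 12 series of one strain, diet and number moved as units it would be 0.00216, or 45.8 features. That figure takes the arrays of a series as identical and the series as interchangeable. Here arrays of a series differed and the numbers stood apart, so 45.8 is not a level to set the 51 against. Among the 462 ways to divide the 12 series evenly, the real one gave 51 such features and the highest other gave 0. A number 3 term gave 3304 on chow and 5235 on high-fat diet, in numbers 1 and 2 alone 2008 and 2521 were called, and in number 3 alone 895 and 5193. With the series as a random block the counts were 271 on chow, 177 higher and 94 lower in C57, and 366 on high-fat diet, 253 higher and 113 lower.

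The diet comparison in C57 set high-fat against chow over weeks 4 to 40, with 12 arrays on each diet. Feature 17767 was 0.35 higher on high-fat diet (SE 0.0714, limma adjusted p = 0.0371). Feature 8454 had a mean of -0.51 ± 0.11 (SD, n = 12) on chow and -0.23 ± 0.16 (SD, n = 12) on high-fat diet, a difference of 0.28 (SE 0.0354, limma adjusted p = 2.46e-05). Feature 17433 differed by -0.24 and feature 3015 by -0.21. Features 17767 and 17433 passed in 23 and 19 of 42 alternatives, and features 8454 and 3015 in 40 and 38. Limma called 10 features, 4 higher and 6 lower on high-fat diet. The number 3 term raised this to 118, and numbers 1 and 2 alone gave 15. Number 3 alone gave 166, of which 1 was among the 10. The count was 42 with quantile normalization, 20 with arrays scaled to one spread and 0 with the series as a random block. With only the arrays of the contrast it was 4, all higher, and features 17767, 17433 and 3015 were not called.

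In C3H the same comparison gave feature 6324 a mean of -1.12 ± 0.17 (SD, n = 12) on chow and -0.57 ± 0.30 (SD, n = 12) on high-fat diet, a difference of 0.55 (SE 0.0810, limma adjusted p = 0.000212). Feature 1212 rose from 0.37 ± 0.19 (SD, n = 12) to 0.89 ± 0.15 (SD, n = 12), by 0.52 (limma adjusted p = 6.11e-05). Feature 11166 differed by -0.35 and feature 5818 by -0.28. Limma called 112 features, 99 higher and 13 lower on high-fat diet, and 103 of them had the same sign in every week. With quantile normalization 58 were called, 36 higher and 22 lower, with arrays scaled to one spread 47, with only the arrays of the contrast 19, and with the series as a random block 0. Adding the number 3 term gave 758, 568 of them higher. In numbers 1 and 2 alone only 16 were called, 9 higher and 7 lower, and 12 of these were among the 112. Number 3 alone gave 1662, which held 64 of the 112. Leaving out single arrays moved the count from 31, without chow replicate 3 at week 4, to 261, without high-fat replicate 1 at week 8.

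No feature was called for diet in both strains, where independent lists would share 0.0187 higher and 0.00368 lower, so the absence says little. Of the 112 features called in C3H, 73 had the same sign in C57, and across all features the diet differences of the strains correlated at -0.228, where features are not independent replicates. The difference itself was tested as an interaction. Feature 5037 was 0.25 higher on high-fat diet in C57 (SE 0.0333) and differed by -0.12 in C3H (SE 0.0333), an interaction of 0.37 (limma adjusted p = 2.78e-05). Feature 8454 differed by 0.28 in C57 and -0.04 in C3H, an interaction of 0.32 (limma adjusted p = 0.00123). Feature 2209 had an interaction of -0.17 (limma adjusted p = 0.0265). The interaction had the same sign in each of the 3 replicate numbers in these features. In all 4 features were called, 3 of them positive, and the fourth, feature 16807, lies outside the naming rule and was chosen after its values were seen. With the number 3 term 101 were called, in numbers 1 and 2 alone 2 and with the series as a random block 0. Number 3 alone gave 967, which held 2 of the 4. Quantile normalization gave 11, of which 4 were positive, and scaling the arrays to one spread 11, of which 5 were positive.

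**Figure D3:**
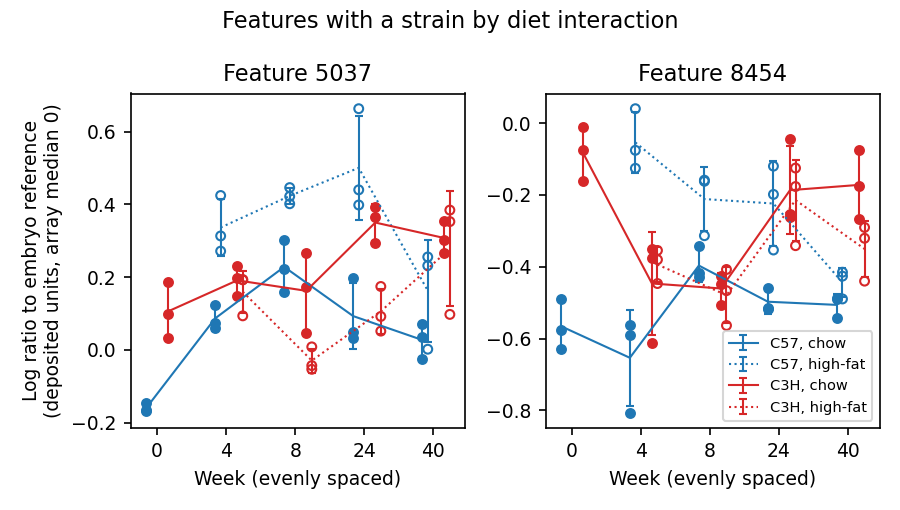
Log ratio to the embryo reference (y axis, deposited units) by week (x axis, evenly spaced) for features 5037 and 8454, with chow as filled points and solid lines and high-fat diet as open points and dotted lines; bars are SDs of 3 arrays. In C57 the high-fat means lie above the chow means at every week on diet, by 0.60 at week 4 and 0.06 at week 40 in feature 8454.

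Single weeks compare 3 arrays with 3, or as few as 2 in a group where a feature was not measured on an array. In C57, limma called 5 features at week 4, 0 at week 8, 1 at week 24 and 3 at week 40. At week 4 feature 17767 was 0.74 higher on high-fat diet, feature 8454 was 0.60 higher, and features 17433 and 1643 differed by -0.54 and -0.49. Feature 5037 was 0.41 higher at week 24, and at week 40 features 13478 and 4020 were 0.55 and 0.39 higher. Feature 13478 averaged 0.74 ± 0.45 (SD, n = 3) on high-fat diet at week 40 and differed by 0.38, 0.31 and 0.98 in numbers 1, 2 and 3. Without high-fat replicate 3 it differed by 0.30 and was not called. It passed in 13 of 23 alternatives and feature 4020 in 10 of 23. At an unadjusted limma p under 0.05, week 8 had 901 features (4.25%), below the share of 0.05 expected with no difference. The main fit holds no term for the number, so spread between numbers can lower such a share. It is then not evidence of no difference. At week 8 in C57 the number 3 term called 51 features, and numbers 1 and 2 alone called 0. In C3H the counts were 0 at week 4, 5 at week 8, 3 at week 24 and 30 at week 40. At week 4 in C3H, 582 features (2.75%) had an unadjusted limma p under 0.05, again below that share and with the same limit. Features 10380 and 5407 were 0.31 and 0.27 higher at week 8, and feature 1212 was 0.75 higher at week 24. Feature 5818 differed by -0.38 at week 8 and -0.39 at week 24. Apart from features 13478 and 4020, these single-week calls passed in 14 to 22 of 23 alternatives. Summed over weeks, limma called 9 in C57 and 38 in C3H, with 6 and 33 higher. With the number 3 term the sums were 137 and 1000, with 65 and 473 higher. In numbers 1 and 2 alone they were 28 and 1509, with only 6 and 395 higher, so the lean of the sums to higher ratios turned there. In C3H the turn came from week 8, which held 1331 of the 1509, 240 higher and 1091 lower. Week 40 held 176, of which 155 were higher. At week 8 in C3H the number 3 term called 495, 131 higher and 364 lower, but quantile normalization called 1 and the series as a random block 0. Summed over weeks, quantile normalization gave 17 in each strain, with 5 higher in C57 and 13 in C3H, against 6 and 33 higher without it. Scaling the arrays to one spread gave 18 and 7, of which 7 and 3 were higher. The series as a random block gave 5 and 0, and only the arrays of the contrast gave 0 in each.

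At week 40 in C3H, 29 of the 30 called features were higher on high-fat diet. Feature 368 was 1.11 higher (SE 0.196) and feature 152 was 1.09 higher (SE 0.227), and feature 8157 differed by -0.19. Values were missing in features 368 and 152. Feature 368 was measured on both diets only in number 3, where it differed by 0.40. Feature 152 was measured on both diets in numbers 1 and 3, with differences of 1.93 and 0.24. In feature 152 the 3 high-fat arrays averaged 0.94 ± 0.81 (SD, n = 3), and the feature passed in 11 of 22 alternatives. Of the 29 features, 23 had numbers up to 2257, a stretch that holds 10.1% of the tested features. Feature numbers were taken to follow the position on the array, which was not checked. The count of higher features was 127 without high-fat replicate 3 and 5 without chow replicate 1. Quantile normalization called 8 features at this week, all among the 29. Scaling the arrays to one spread, the series as a random block and only the arrays of the contrast each gave 0. With the number 3 term 492 were called, 337 of them higher, and in numbers 1 and 2 alone 176, of which 155 were higher.

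**Figure D4:**
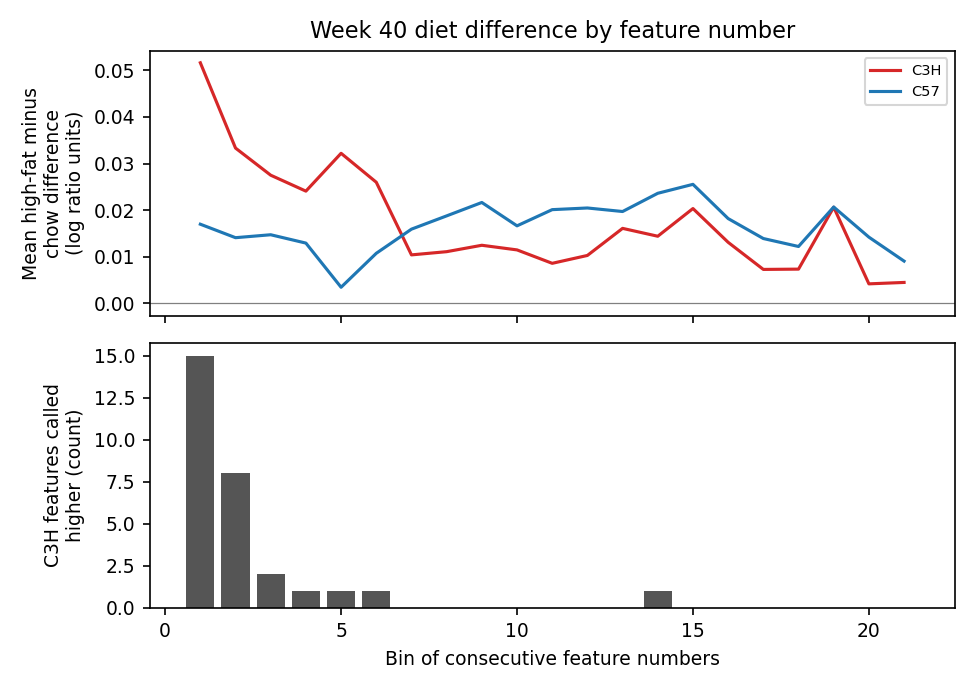
Week 40 diet difference by feature number, in 21 bins of consecutive feature numbers (x axis): mean difference of all tested features per strain in log ratio units (top) and number of C3H features called higher on high-fat diet (bottom). The bins with the lowest numbers hold most of the 29 called features, and the C3H mean is highest there.

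Time was compared on chow as week 40 minus week 0. In C57 feature 299 went from 0.18 ± 0.12 (SD, n = 3) to -0.55 ± 0.12 (SD, n = 3), a difference of -0.73 (SE 0.126). In C3H it differed by -0.63 (SE 0.126). Feature 11462 differed by -0.71 in C57 and -0.62 in C3H. Their limma adjusted p-values were 0.00252 and 0.00143 in C57 and 0.0148 and 0.00790 in C3H. Features 299 and 11462 passed in 21 and 22 of 23 alternatives in C57, but in 14 and 19 of 23 in C3H. In C3H feature 20060 rose by 1.05 (SE 0.174, limma adjusted p = 0.00118) and feature 10890 by 0.59 (SE 0.118, limma adjusted p = 0.0144). They passed in 23 and 18 of 23 alternatives. Feature 20060 also rose in C57, by 0.33 from week 0 to week 4 and 0.36 from week 4 to week 40, but was not called there. Limma called 13 features in C57, all lower at week 40, and 21 in C3H, 5 higher and 16 lower. Quantile normalization gave 25 in C57, 3 of them higher. The lists shared 11 features, all lower, where independent lists would share 0.00982. The number 3 term gave 82 and 139, and numbers 1 and 2 alone gave 29 and 50. With only the arrays of the contrast and their own spread, 0 and 1 were called. The count in C3H was 33 without chow replicate 3 at week 0, 13 without replicate 1 at week 0 and 13 without replicate 2 at week 40.

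The change over time did not pass the test for a strain difference in any feature: limma called 0. At an unadjusted limma p under 0.05 there were 393 features (1.86%), below the share of 0.05 expected with no difference. Spread between numbers, for which this fit holds no term, can lower that share. The number 3 term and numbers 1 and 2 alone also gave 0. Any change over the 5 chow weeks was called in 15 features in C57 and 30 in C3H, and 14 were in both lists, where independent lists would share 0.0212. The F test with the number 3 term called 91 and 174, in numbers 1 and 2 alone 28 and 47, with quantile normalization 30 in C57, and with only the arrays of the contrast 2 and 5.

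**Figure D5:**
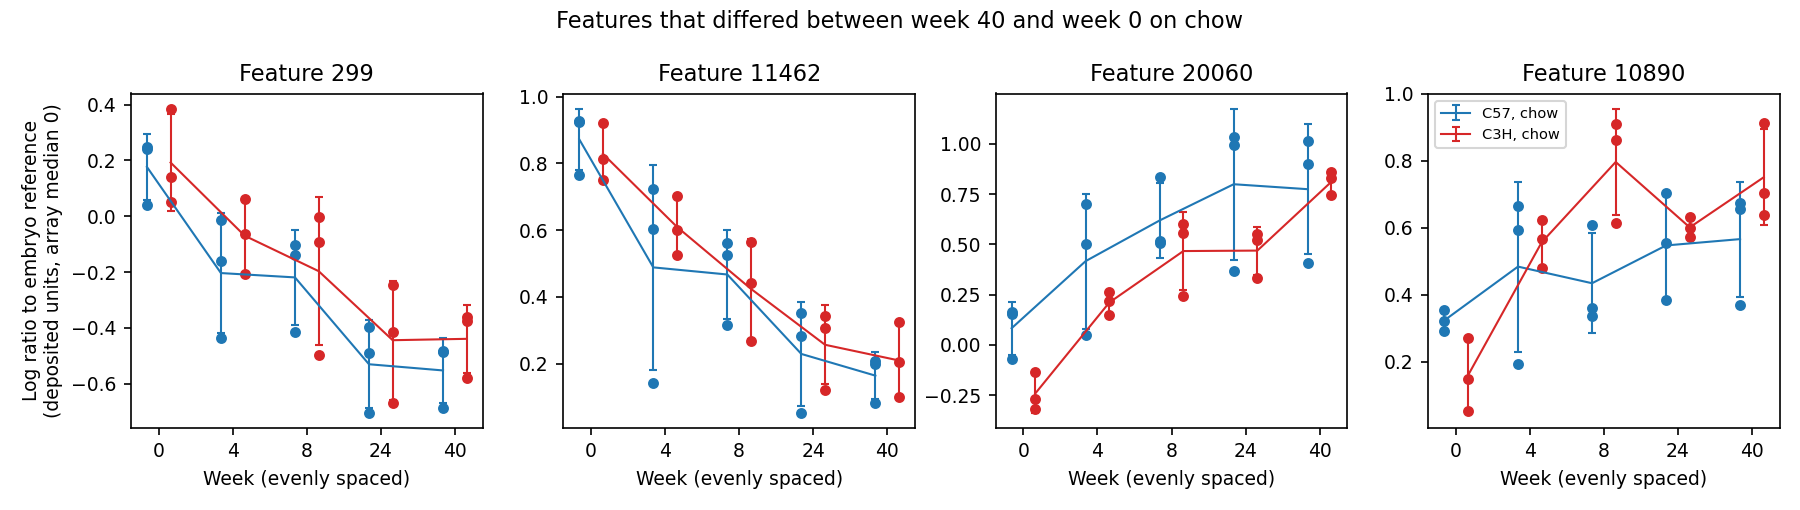
Log ratio to the embryo reference on chow (y axis, deposited units) by week (x axis, evenly spaced) for 4 features; points are arrays, lines join the means of 3 arrays and bars are SDs. Features 299 and 11462 fell by 0.73 and 0.71 between weeks 0 and 40 in C57. Feature 20060 rose in both strains, by 1.05 in C3H.

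The diet difference at week 40 was also set against that at week 4. In C57 it changed by 0.60 in feature 1643 (SE 0.0870, limma adjusted p = 0.000523), from -0.49 at week 4 to 0.11 at week 40. In feature 8454 it changed by -0.54 (limma adjusted p = 0.0407), from 0.60 to 0.06. Feature 1643 passed in 28 of 29 alternatives and feature 8454 in 14, not with quantile normalization or arrays scaled to one spread. These 2 were the only features called in C57, and limma called 0 in C3H. With only the arrays of the contrast 0 were called in C57. At an unadjusted limma p under 0.05 there were 687 features in C57 (3.24%) and 925 in C3H (4.37%). Both lie below the share of 0.05 expected with no difference. Spread between numbers, for which this fit holds no term, can lower both. With the number 3 term 18 and 1 were called, and in numbers 1 and 2 alone 86 and 21. The count in C3H was 41 without high-fat replicate 3 at week 40.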

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

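Tests of the arrays numbered 3 as one batch, and of the diet counts under other scalings, without the 5 arrays of small range and by array number, were chosen after the results they measure were seen. Splits that move whole series, or keep 1 array numbered 3 in each group, were chosen after the first splits were seen; the other tests were set down before they were run. In 4 features the diet difference itself differed between strains by the interaction test. The interaction was 0.37 in feature 5037, 0.32 in feature 8454, -0.17 in feature 2209 and 0.26 in feature 16807 (limma adjusted p = 0.0491). Over the alternatives, which include array weights that did not converge, the limma adjusted p ran from 2.62e-08 to 0.756 in feature 5037, from 4.34e-06 to 0.9998 in feature 8454 and from 3.33e-05 to 0.9998 in feature 2209. In 2 features the diet difference in C57 changed between week 4 and week 40, by 0.60 in feature 1643 and by -0.54 in feature 8454. Over the alternatives the limma adjusted p ran from 3.33e-09 to 0.9999 in feature 1643, which passed in 28 of 29, and from 0.00012 to 0.9999 in feature 8454, which passed in 14. Of 100 splits of the diet labels within strain and week, 3 gave at least 4 interaction calls, the real one included, so chance is excluded at that share if arrays vary independently. The highest other split called 7305 features and had the arrays numbered 3 unevenly placed, which points to a structure of the samples. With 1 array numbered 3 kept in each group, 1 of 100 splits, the real one, reached 4 and the highest other gave 2. Arrays of one series, however, correlated at 0.467 across groups once group means were removed, in a fit without a term for the number. When whole series were moved, 41 of 100 splits reached 4 (highest other 11780), and 9 of the 41 splits that kept number 3 even did (highest other 163), so chance is not excluded at the level of series. With the series as a random block the interaction count was 0, and in numbers 1 and 2 alone 2. For the change with time in C57, 12 of 100 splits gave at least 2 calls (highest other 1604), and with number 3 kept even 11 of 100 (highest other 7), so chance is not excluded.

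The strain counts stood far above other splits of single arrays. On chow 1 of 100 splits, the real one, reached 1475 and the highest other gave 123; on high-fat diet 1 of 100 reached 2336 and the highest other gave 183, so chance is excluded for both if arrays vary independently. Whole series give 10 splits, too few for a share under 0.05: 5 reached the count on chow (highest other 7908) and 5 on high-fat diet (highest other 7612). All of these but the real one had number 3 unevenly placed, and the highest other splits with number 3 even gave 19 and 324. With the series as a random block 271 and 366 were called. For the averaged diet difference, 2 of 100 splits reached 10 in C57 with a highest other of 264, and 1 of 100 reached 112 in C3H with a highest other of 81. With number 3 kept even, 2 of 100 splits reached 10 (highest other 184) and 1 of 100 reached 112 (highest other 14), so chance is excluded at these shares if arrays vary independently. The split that gave 264 had the arrays numbered 3 unevenly placed; with a term for number 3 the real counts were 118 and 758. The 10 splits of whole series are again too few: 6 reached 10 (highest other 7252) and 6 reached 112 (highest other 7137). Of the splits with number 3 even, 2 in each strain did, the real one included, with highest others of 33 and 382, and both counts were 0 with the series as a random block. Single weeks are weaker: 13 of 100 splits reached the sum of 9 in C57 (highest other 28) and 8 of 100 the sum of 38 in C3H (highest other 1299), and chance is not excluded over such splits. In 12 and 7 of those splits, all but the real one, the arrays numbered 3 fell unevenly. With number 3 kept even, 4 of 100 reached 9 (highest other 10) and 2 of 100 reached 38 (highest other 39), which excludes chance at these shares for independent arrays in that narrower set. With a term for number 3 the sums were 137 and 1000, and with the series as a random block 5 and 0. Any change over the 5 chow weeks was reached by 4 of 100 splits in C57 (15 features, highest other 674) and 1 of 100 in C3H (30 features, highest other 16). The 10 splits of the baseline comparison and of each time comparison are too few for a share under 0.05: real counts were 113, 13 and 21, each reached by 1 split, and the highest other was 0 in each. For strain by time and for the change with time in C3H the real count was 0, which all 100 splits reached, with highest others of 5 and 4693.

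The first pattern is the separation of the arrays numbered 3, which differed from the others in 14408 of 20694 features by limma with Benjamini-Hochberg adjustment. A different spread of values between arrays is argued against, since after quantile normalization the gap on the first component was still 2.66. Position on the assumed array grid is argued against too, with a gap of 3.56 after local medians were removed. A batch shared by the arrays numbered 3 was not put to a test that could decide it: their mean deviation in C57 and in C3H correlated at 0.809 across features, which restates that they lie on one side of the first component in both strains. The labels give no group that follows the number, so no biological explanation was tested.

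The second pattern is the crowding of the C3H week 40 features at the lowest numbers. The 612 uncalled features around the called ones on the assumed grid averaged 0.102. The middle 95% of 10000 random sets lay at 0.00954 to 0.0242, so position on the array may account for part of the crowding. After local medians were removed, 14 of the 29 features stayed called, 9 of the 14 with numbers up to 2257, so the correction did not end the crowding, and the median difference of the 29 went from 0.48 to 0.39. A single array as the source cannot be told apart among the arrays numbered 1 and 2. Leaving out 1 of the 6 arrays left at least 3 higher features with numbers up to 2257 but fewer than 10 in some cases. There were 77 such features without high-fat replicate 3 and 17 without chow replicate 3. In numbers 1 and 2 alone 27 of the 29 stayed called, which argues against an array numbered 3 as the single source. An effect of diet in C3H at week 40 stays open, but 8 features were called there with quantile normalization and 0 with arrays scaled to one spread, with the series as a random block or with only the arrays of the contrast.

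The third pattern is the lower diet count in C57 than in C3H, 10 against 112. With quantile normalization the counts were 42 and 58, a ratio of 1.38 in place of 11.2, and with arrays scaled to one spread 20 and 47, a ratio of 2.35, so a different spread of values between arrays may account for part of the gap. The arrays numbered 3 as its source cannot be told apart: in numbers 1 and 2 alone the counts were 15 and 16, a ratio of 1.07, and in number 3 alone 166 and 1662, but with a term for number 3 they were 118 and 758, a ratio of 6.42. The 5 arrays of small range alone are argued against, since without them the counts were 14 and 89, a ratio of 6.36. A strain difference in the response to diet stays open. Its direct test called 4 features, and 0 with the series as a random block. That block holds no term for the number, so the spread between numbers enters it and its 0 cannot decide the question.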

How the results depend on the processing

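Zeros kept as values, the term for number 3, numbers 1 and 2 alone, number 3 alone, the 5 arrays of small range, the scaling to one spread, the removal of local medians, the repeated features and the weights fitted feature by feature were tests chosen after seeing the data. Named features kept their direction under all alternatives run: apart from left-out arrays, 727 values stayed past the limma threshold and 106 did not, 28 of them with only the arrays of the contrast and 24 with the series as a random block. With single arrays left out, 616 stayed past it and 122 did not. Counts stayed within 1.5 times with no centring, features measured on all 54 arrays only, no filter, exact zeros kept and the repeated features left out. Why counts moved was not tested, except that fewer arrays enter where arrays are left out. Signal over background was not used, so what it limits was not assessed. Number 3 alone gave no value for baseline, single weeks, changes over time and the F tests. Without gene names, averaging the probes of a gene and the gene list tests with camera and fry were not run.

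The replicate numbers were checked for pairing. Of 459 pairs of same-numbered arrays in different groups, 381 had deviations from the group means that correlated over 0.1, the lowest at -0.462 and the median at 0.369, against a median of -0.242 for different numbers. In 48 of 54 arrays the mean correlation was highest with the array's own number, a hint from the data and not from the design. The numbers therefore do not count as pairs. With the replicate number as a fixed block, limma called 441 for the strain difference at baseline, 3464 for the strain difference on chow, 5433 for the strain difference on high-fat diet, 124 for the diet difference in C57, 864 for the diet difference in C3H, 134 for the strain by diet interaction, 164 for the diet difference at each week in C57, 1273 for the diet difference at each week in C3H, 77 for the time difference on chow in C57, 153 for the time difference on chow in C3H, 28 for the change of the diet difference with time in C57, 4 for the change of the diet difference with time in C3H, 99 for any change over the 5 weeks on chow in C57 and 202 for any change over the 5 weeks on chow in C3H. In the comparisons between groups, all features called without the block were also called with it; for the F tests this was not counted.

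With quantile normalization, limma called 42 for the diet difference in C57, 58 for the diet difference in C3H, 11 for the strain by diet interaction, 17 for the diet difference at each week in C57, 17 for the diet difference at each week in C3H, 25 for the time difference on chow in C57 and 30 for any change over the 5 weeks on chow in C57. With the 12 series as a random block, limma called 271 for the strain difference on chow, 366 for the strain difference on high-fat diet, 0 for the diet difference in C57, 0 for the diet difference in C3H, 0 for the strain by diet interaction, 5 for the diet difference at each week in C57, 0 for the diet difference at each week in C3H, 77 for the time difference on chow in C57, 176 for the time difference on chow in C3H, 6 for the change of the diet difference with time in C57, 12 for the change of the diet difference with time in C3H, 62 for any change over the 5 weeks on chow in C57 and 214 for any change over the 5 weeks on chow in C3H. With the planned array weights, limma called 2481 for the strain difference at baseline, 5084 for the strain difference on chow, 5386 for the strain difference on high-fat diet, 504 for the diet difference in C57, 1731 for the diet difference in C3H, 1295 for the strain by diet interaction, 15815 for the diet difference at each week in C57, 16425 for the diet difference at each week in C3H, 259 for the time difference on chow in C57, 631 for the time difference on chow in C3H, 29 for the strain by time interaction on chow, 369 for the change of the diet difference with time in C57, 433 for the change of the diet difference with time in C3H, 16606 for any change over the 5 weeks on chow in C57 and 5133 for any change over the 5 weeks on chow in C3H. These weights stopped before convergence, with values from 0.144 to 60.9, and the counts are not reliable. With a trended and robust variance prior, limma called 2 for the strain by diet interaction and 1 for the change of the diet difference with time in C57. With only the arrays of the contrast, limma called 31 for the strain difference at baseline, 4 for the diet difference in C57, 19 for the diet difference in C3H, 0 for the diet difference at each week in C57, 0 for the diet difference at each week in C3H, 0 for the time difference on chow in C57, 1 for the time difference on chow in C3H, 0 for the change of the diet difference with time in C57, 2 for any change over the 5 weeks on chow in C57 and 5 for any change over the 5 weeks on chow in C3H. With array weights fitted feature by feature, limma called 1131 for the strain difference at baseline, 3231 for the strain difference on chow, 64 for the diet difference in C57, 437 for the diet difference in C3H, 51 for the strain by diet interaction, 2300 for the diet difference at each week in C57, 2934 for the diet difference at each week in C3H, 85 for the time difference on chow in C57, 290 for the time difference on chow in C3H, 1 for the strain by time interaction on chow, 40 for the change of the diet difference with time in C57, 54 for the change of the diet difference with time in C3H, 2449 for any change over the 5 weeks on chow in C57 and 653 for any change over the 5 weeks on chow in C3H. With the 5 arrays of small range left out, limma called 10 for the strain by diet interaction and 1 for the change of the diet difference with time in C57. With arrays scaled to one spread, limma called 20 for the diet difference in C57, 47 for the diet difference in C3H, 11 for the strain by diet interaction, 18 for the diet difference at each week in C57, 7 for the diet difference at each week in C3H and 1 for the change of the diet difference with time in C57. With local medians on the array grid removed, limma called 21 for the diet difference at each week in C3H, 32 for the time difference on chow in C3H and 1 for the change of the diet difference with time in C57. With a term for number 3, limma called 411 for the strain difference at baseline, 3304 for the strain difference on chow, 5235 for the strain difference on high-fat diet, 118 for the diet difference in C57, 758 for the diet difference in C3H, 101 for the strain by diet interaction, 137 for the diet difference at each week in C57, 1000 for the diet difference at each week in C3H, 82 for the time difference on chow in C57, 139 for the time difference on chow in C3H, 18 for the change of the diet difference with time in C57, 1 for the change of the diet difference with time in C3H, 91 for any change over the 5 weeks on chow in C57 and 174 for any change over the 5 weeks on chow in C3H. With only arrays numbered 1 and 2, limma called 16 for the diet difference in C3H, 2 for the strain by diet interaction, 28 for the diet difference at each week in C57, 1509 for the diet difference at each week in C3H, 29 for the time difference on chow in C57, 50 for the time difference on chow in C3H, 86 for the change of the diet difference with time in C57, 21 for the change of the diet difference with time in C3H, 28 for any change over the 5 weeks on chow in C57 and 47 for any change over the 5 weeks on chow in C3H. With only arrays numbered 3 and week as an additive term, limma called 895 for the strain difference on chow, 5193 for the strain difference on high-fat diet, 166 for the diet difference in C57, 1662 for the diet difference in C3H and 967 for the strain by diet interaction.

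For the strain difference at baseline, leaving out arrays gave 57 to 87, over 1.5 times off without C3H chow week 0 replicate 2 (65) and C57 chow week 0 replicate 1 (65), 2 (67) and 3 (57). Left-out arrays took the strain difference on chow from 1333 to 1520. For the strain difference on high-fat diet, leaving out arrays gave 1878 to 2492. Left-out arrays took the diet difference in C57 from 5 to 14, over 1.5 times off without C57 chow week 4 replicate 2 (5), C57 chow week 8 replicate 2 (6), C57 chow week 24 replicate 2 (6), C57 chow week 40 replicate 2 (6), C57 high-fat week 4 replicate 2 (6) and C57 high-fat week 8 replicate 2 (6). For the diet difference in C3H, leaving out arrays gave 31 to 261, over 1.5 times off without C3H chow week 8 replicate 1 (42) and 2 (57), C3H chow week 24 replicate 1 (37), 2 (249) and 3 (49), C3H chow week 40 replicate 1 (58) and 2 (52), C3H high-fat week 4 replicate 1 (197) and 3 (40), C3H high-fat week 8 replicate 1 (261), 2 (51) and 3 (43), C3H high-fat week 24 replicate 1 (172), 2 (55) and 3 (46), C3H high-fat week 40 replicate 1 (201) and 3 (60) and C3H chow week 4 replicate 3 (31). Left-out arrays took the strain by diet interaction from 2 to 12, over 1.5 times off without C57 chow week 4 replicate 2 (2) and 3 (12), C57 chow week 40 replicate 2 (2) and 3 (2), C3H chow week 4 replicate 2 (2) and 3 (2), C57 chow week 24 replicate 2 (2), C3H chow week 8 replicate 2 (2), C3H chow week 40 replicate 2 (7), C57 high-fat week 8 replicate 2 (2) and 3 (2), C57 high-fat week 24 replicate 1 (2) and C3H chow week 24 replicate 3 (2). For the diet difference at each week in C57, leaving out arrays gave 5 to 54, over 1.5 times off without C57 chow week 4 replicate 2 (5) and 3 (16), C57 high-fat week 8 replicate 2 (19) and C57 high-fat week 40 replicate 1 (54) and 2 (51). Left-out arrays took the diet difference at each week in C3H from 14 to 164, over 1.5 times off without C3H chow week 24 replicate 2 (59), C3H chow week 40 replicate 1 (14) and 2 (21), C3H high-fat week 40 replicate 1 (21) and 3 (164) and C3H high-fat week 24 replicate 1 (63). For the time difference on chow in C57, leaving out arrays gave 9 to 18. Left-out arrays took the time difference on chow in C3H from 13 to 33, over 1.5 times off without C3H chow week 40 replicate 2 (13) and C3H chow week 0 replicate 1 (13) and 3 (33). For the strain by time interaction on chow, leaving out arrays gave 0 to 1, over 1.5 times off without C57 chow week 40 replicate 1 (1). Left-out arrays took the change of the diet difference with time in C57 from 1 to 3, over 1.5 times off without C57 chow week 40 replicate 1 (1), 2 (1) and 3 (1), C57 chow week 4 replicate 2 (1), C57 high-fat week 4 replicate 1 (1) and 2 (1) and C57 high-fat week 40 replicate 2 (1) and 3 (1). For the change of the diet difference with time in C3H, leaving out arrays gave 0 to 41, over 1.5 times off without C3H high-fat week 40 replicate 3 (41). Left-out arrays took any change over the 5 weeks on chow in C57 from 6 to 20, over 1.5 times off without C57 chow week 0 replicate 1 (6), 2 (6) and 3 (8). For any change over the 5 weeks on chow in C3H, leaving out arrays gave 16 to 43, over 1.5 times off without C3H chow week 0 replicate 1 (16).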

Other observations

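On high-fat diet, time could be followed from week 4 to week 40. Limma called 28 features in C57, 25 higher and 3 lower at week 40, and 17 in C3H, 16 higher and 1 lower. On chow over the same weeks it called 0 in C57 and 11 in C3H. From week 0 to week 4 on chow it called 2 in C57, both lower, and 12 in C3H, 5 higher and 7 lower. These comparisons were added after the data were seen. No counts with the number 3 term, from numbers 1 and 2 alone or with single arrays left out are given for them. At week 40 the C57 high-fat replicate 3 correlated with the other arrays at a median of 0.698, against 0.808 and 0.865 for replicates 1 and 2. The difference between the high-fat and the chow change from week 4 to week 40 is the change of the diet difference with time, which limma called in 2 features in C57 and 0 in C3H. Features 299 and 11462, which had lower ratios at week 40 than at week 0 on chow, had chow differences of -0.38 and -0.38 by week 4 in C57 and of -0.26 and -0.22 in C3H, none of them past the limma threshold on its own.

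Feature 17433 had a ratio of 0.65 ± 0.05 (SD, n = 3) in C57 and -0.02 ± 0.06 (SD, n = 3) in C3H at week 0, and the strain difference ran from -0.51 to 0.67 over the 9 conditions. Feature 8454 likewise ran from -0.48 to 0.34. The 147 features with near-identical values had a median SD over arrays of 0.203 and sat at regular numbers, none of them named in the annotation.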
